A study of Ovis aries with 32 samples.

How the data were processed

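Transcriptomes of Tan sheep, a fat-tailed Chinese breed, were measured by RNA sequencing in tissue labelled hypothalamus, pituitary, liver and tail adipose tissue (tail fat). Per the series' design text, 24 male sheep aged 3 months were divided into 2 diets of 12 sheep each. One diet was the basal pellet (CON) and the other was the same pellet with succinic acid (SA), an intermediate of the tricarboxylic acid cycle, at 1% of the dry matter. The diets were fed for 60 days after 10 days of adaptation. Each of the 8 groups of tissue and diet held 4 libraries, 32 in total. The labels do not say whether libraries with the same number in different tissues came from the same sheep.

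Per the labels' protocols, RNA was extracted with TRIzol, messenger RNA was captured on oligo(dT) beads, stranded libraries were made with an Illumina kit, and sequencing was done on a NovaSeq instrument. Per the submitters' processing notes, fastp, HISAT2 and RSEM were used, and their versions, the genome build, the annotation and the strand setting of the counting are not given in the sources used here. The gene identifiers are Ensembl identifiers of sheep. The values deposited by the authors are TPM, in which the abundance of transcripts is scaled to a sum of 1000000 per library, estimated within each library and rounded to 2 decimals, with no scaling between libraries. TPM keeps no record of sequencing depth, so the depth of each library is unknown and no counting interval can be given. The columns summed to between 936939 and 987320 TPM rather than 1000000. Because TPM is relative, a set of transcripts that takes a larger share of a library lowers the values of all other genes. The table also held 8 columns of group means, which equalled the means of their 4 libraries and were not used.

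The table had 30722 rows, of which 13350 had no gene name. Symbols were taken from the table itself. Where 64 names stood on more than 1 row, the row with the highest mean kept the plain symbol. A RefSeq gene table of the sheep assembly ARS-UI_Ramb_v3.0 held no Ensembl identifiers and was used only to see which genes overlap or neighbour each other.

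The test was fixed before the data were examined, with a version for counts and a version for TPM, and the TPM version applied. In each tissue, genes at 1 TPM or more in at least 4 of the 8 libraries were tested on log2(TPM + 1) with limma (version 3.58.1 in R 4.3.3), using empirical Bayes moderation with a mean trend and robust settings. P-values were two-sided and adjusted by the Benjamini-Hochberg method over all genes tested in the tissue, with a threshold of 0.05. Changes are SA minus CON on the log2(TPM + 1) scale with their standard errors (SE), and this scale understates the change of genes of low expression. Levels are given as mean ± SD over n = 4 libraries. Each tissue was fitted alone. Whether the effect of diet differed between tissues was tested with a limma F-test of the interaction, with 3 degrees of freedom, over all 32 libraries and the genes that passed the filter in any tissue.

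Before the data were examined, 49 gene lists of pathways and cell type markers were written from general knowledge. In each tissue the lists that apply and have at least 3 tested members were tested with camera at a preset correlation between genes of 0.01. Camera asks whether the members of a list moved relative to all other tested genes. Each list test was repeated with a correlation estimated from the libraries and with fry, which tests whether the members of a list moved on balance in 1 direction without comparing them with other genes. Adjusted p-values of lists cover the lists run in that tissue. Counts of members past the threshold are given over all genes tested and, where stated, adjusted over the list alone.

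The genes named in the text were also chosen by a rule fixed beforehand. The rule took a panel of genes for each tissue whatever their result, the 10 genes with a symbol and the smallest p in each direction among those past the threshold, and up to 4 members past the threshold from each list. Where fewer than 5 genes passed, it took the 5 genes of smallest p in each direction, described as not passing. Members of lists that did not pass are given as examples with their values. A few other genes were chosen after their values were seen, and the text says so.

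The tests were run first on simulated data built on the values of these libraries. With 4 libraries per diet, the simulated test recovered 77% of genes changed by 1 on the log2 scale and 94% of those changed by 2 in the libraries labelled hypothalamus. The corresponding shares were 10% and 71% for the libraries labelled pituitary, 41% and 79% for liver, and 0% and 7% for tail fat. The number of unchanged genes called was 5, 3, 4 and 0 in that order. In all simulations the changed genes were drawn from those with a mean log2(TPM + 1) over 2. Noise was drawn independently for each gene, without differences shared by the genes of a library, so real false calls can be more frequent. For the interaction, 200 genes were changed by 2 in the libraries labelled hypothalamus only. Data simulated with the spread each gene has in each tissue gave 79.5% recovery of them, with 109 false calls among 16360 genes. A simulation added afterwards, with 1 spread per gene in all tissues, gave 84% and 4 false calls. The interaction count can therefore hold false calls from spreads that differ between tissues.

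Each result was recomputed under other settings. Those fixed beforehand were quantile normalization, no filter beyond a total above 0, a filter at 5 TPM, a pseudocount of 0.1, array weights, all 32 libraries in a joint fit, the replicate number as a block, the other list tests and leaving out each library in turn. Settings chosen after seeing the data were the removal of mitochondrially encoded and ribosomal RNA rows with rescaling to 1000000, a tail fat fit on 6 libraries, a tail fat fit with a library state as a covariate, and several settings of the interaction and of the overlap between tissues. The replicate numbers were taken from the labels. A few comparisons of single values between groups of 4 used exact permutation tests. Figures and permutation tests were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.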

Results

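Gene expression was measured in 32 RNA-seq libraries of Tan sheep fed a basal diet (CON) or the same diet with 1% succinic acid (SA). Tissue labelled hypothalamus, pituitary, liver and tail fat gave 4 libraries per diet each. The values are TPM, so the sequencing depth behind them is unknown, and the columns summed to between 936939 and 987320.

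Libraries of the same tissue differed in composition. Mitochondrially encoded transcripts held 20.2% to 27.8% of TPM in the 4 liver CON libraries and 51.7% to 70.9% in the 4 liver SA libraries. The difference of 35.6 percentage points had an exact permutation p of 0.0286, the smallest that 4 against 4 libraries allow, and an adjusted p of 0.114 over the 12 comparisons of this kind. The liver SA libraries also had fewer genes at 1 TPM or more (10216 to 10611 against 11504 to 12057), with the same exact p. In tail fat the mitochondrial share ranged from 22.5% to 70.6% in CON and from 25.6% to 50.2% in SA. CCDC152 (ENSOARG00020006118), which lies next to the selenoprotein P gene SELENOP, was listed at 0 in all liver CON libraries and stood at 168 to 842 TPM in all liver SA libraries. In tail fat it was at 57.8 to 162 TPM in 3 CON libraries but at 0.12 in CON 2, and at 148 to 186 TPM in 3 SA libraries but at 0.07 in SA 1. SELENOP went the other way, at 4282 to 5758 TPM in liver CON and 241 to 773 in liver SA, and at 972 in tail fat CON 2 and 598 in tail fat SA 1 against 46.0 to 197 in the other 6 tail fat libraries. In the brain libraries CCDC152 did not exceed 0.08 TPM.

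**Figure D1:**
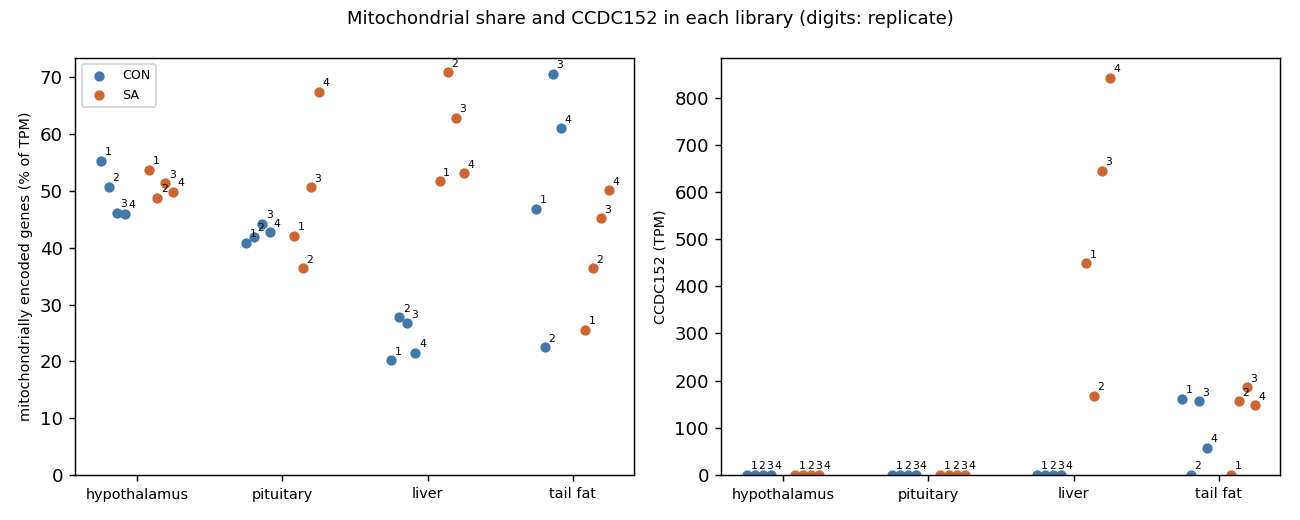
Share of TPM from mitochondrially encoded transcripts (percent) and TPM of CCDC152 in each of the 32 libraries, by tissue and diet, with the digit giving the replicate number. Liver SA libraries lie between 51.7% and 70.9% and liver CON libraries between 20.2% and 27.8%, while in tail fat CON 2 and SA 1 lie apart from the other 6 libraries.

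The libraries labelled hypothalamus and pituitary held brain transcripts with low levels of the hormones that define these tissues. In the 8 libraries labelled hypothalamus, AVP averaged 0.41 TPM, HCRT 1.75 and POMC 2.39, whereas PPP1R1B, a signalling protein abundant in striatal neurons, averaged 1512 ± 302 TPM (SD, n = 8), PENK 1062 and the dopamine receptor DRD1 145. In the 8 libraries labelled pituitary, PRL averaged 0.26 TPM, POMC 3.60 and the shared hormone subunit CGA was listed at 0, whereas SNAP25, a synaptic protein, averaged 1155 ± 146 TPM in CON and 908 ± 422 in SA (n = 4 each). The region markers were listed after some of these values had been seen. GH1 and LHB were not found by name and were not analysed here.

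**Figure D2:**
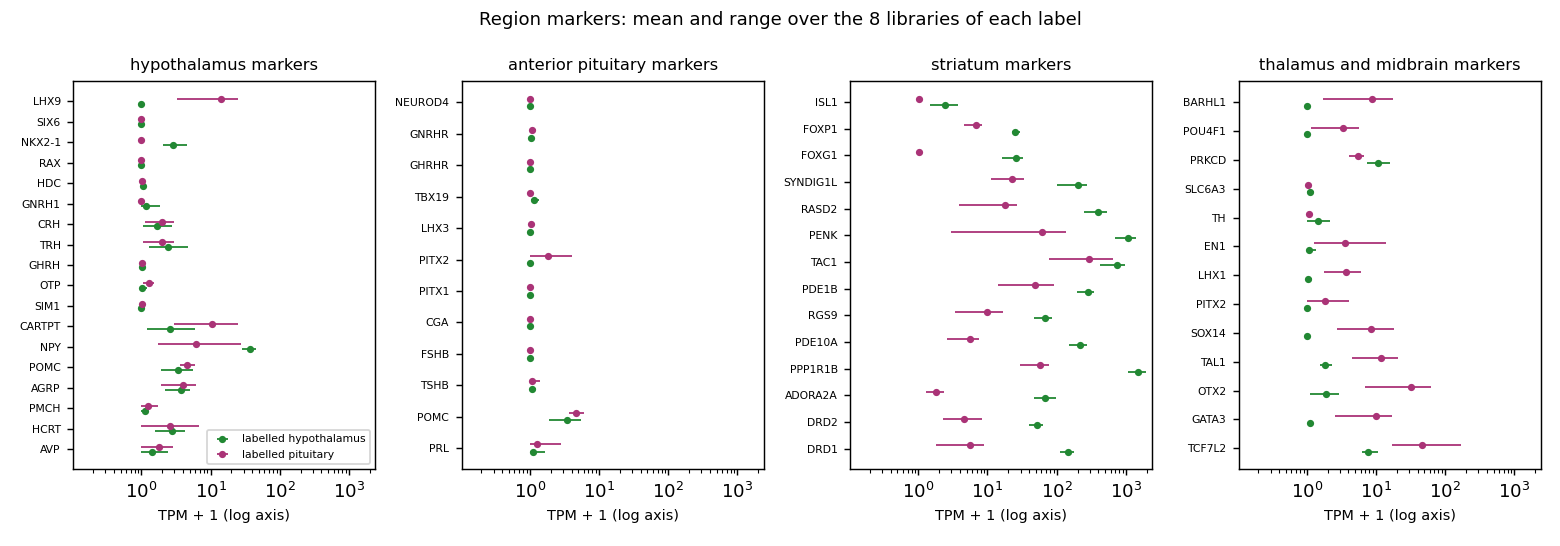
Mean TPM + 1 (log axis) and range over the 8 libraries of each brain label for marker genes of hypothalamus, anterior pituitary, striatum, and thalamus and midbrain. Striatum markers such as PPP1R1B and DRD1 were high in the libraries labelled hypothalamus, and anterior pituitary hormones were low under both labels.

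The first comparison asked whether dietary succinic acid altered expression in tissue labelled hypothalamus, which in sheep controls feed intake and hormone release. Genes of myelin, the insulating sheath made by oligodendrocytes, were lower with SA as a group, with 18 of 19 measured members lower and a median change of −0.83 (camera, adjusted p = 1.05e-08, and adjusted p = 0.922 with an estimated correlation). The calls of all 8 lists that passed in these libraries were lost in that way, each with an adjusted p = 0.922 with an estimated correlation. Myelin basic protein MBP averaged 6198 ± 4473 TPM in CON and 2009 ± 991 in SA (change −1.48, SE 0.59), and MOBP went from 1380 to 577. Markers of macrophages and microglia, the resident immune cells of the brain, were higher in all 14 measured members (adjusted p = 4.48e-05, and 0.922 as adjusted p with an estimated correlation), among them the chemokine receptor CX3CR1 (change 0.43), the complement gene C1QA (0.54) and CSF1R (0.43). Neuropeptides and receptors of feeding were higher in 15 of 17 members (adjusted p = 0.0479, and 0.922 in the same way), with PDYN, the dynorphin precursor, changing by 0.83, CARTPT by 0.82 and CCK by 0.43. This list shares PENK and TAC1 with the striatum markers, which were high in these libraries, while hypothalamic hormones were low. The list therefore does not name the cells or show a change in hypothalamic control of feeding.

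Of the other lists in these libraries, all at an adjusted p = 0.922 with an estimated correlation, interferon-stimulated genes were higher in 17 of 19 members (adjusted p = 0.00814), with MX2 at 1.83 TPM in CON and 4.17 in SA and MX1 at 3.56 and 5.64. Markers of ependyma and choroid plexus, which line the ventricles, were higher in 8 of 10 members (adjusted p = 0.0120). Transthyretin TTR, made by choroid plexus, averaged 72.3 ± 101 TPM in CON and 820 ± 1050 in SA, with 2384 in SA 2 and 174 to 479 in the other SA libraries. Neuronal and synaptic genes were higher in 22 of 28 members (adjusted p = 0.0271), such as the growth cone gene GAP43 (0.40). Ribosomal proteins were lower in 28 of 32 members (adjusted p = 0.00264), with RPL19 at 301 TPM in CON and 256 in SA, and endothelial markers were lower in 13 of 15 (adjusted p = 0.00919), with TIE1 at 7.18 and 4.59. No member of these 8 lists passed over all genes or adjusted over the list alone. The myelin genes were uneven within CON, where MBP stood at 11797 and 7810 TPM in CON 3 and CON 4 and at 2801 and 2385 in CON 1 and CON 2. Of the 30 lists tested, 8 passed with all libraries, 3 without CON 3, 3 without CON 4 and 5 without SA 2. After quantile normalization ribosomal proteins (adjusted p = 0.234) and feeding genes (0.0592) no longer passed and glycolysis passed as higher (0.0104). After removal of mitochondrial and ribosomal RNA neuronal genes no longer passed (0.0752).

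No single gene passed the threshold in limma among 14126 tested in the libraries labelled hypothalamus. There were 493 genes with an unadjusted p under 0.05, where chance alone gives 706, and the joint fit of all 32 libraries called 3. The smallest adjusted p, 0.276, belonged to PPM1E (ENSOARG00020016007), a protein phosphatase, at 7.89 ± 1.99 TPM in CON and 24.0 ± 4.68 in SA (change 1.50, SE 0.19). The next genes with higher values were CSTL1 (change 1.11), the forebrain transcription factor EMX2 (1.17), PLEKHF2 (0.52) and TNNI3 (0.78). Those with lower values were MMGT1 (−1.30), hemopexin HPX (−0.43), a signal recognition particle RNA (−1.08), the histone gene H2AC6 (−1.06) and CAVIN2 (−0.96). Their adjusted p-values lay between 0.688 and 0.947. The appetite peptide NPY averaged 33.8 ± 7.32 TPM in CON and 38.0 ± 4.65 in SA, somatostatin SST 129 ± 30.1 and 165 ± 36.4, and AGRP 2.71 and 2.87. POMC and TRH did not pass either, and CRH and GHRH lay below the expression filter.

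**Figure D3:**
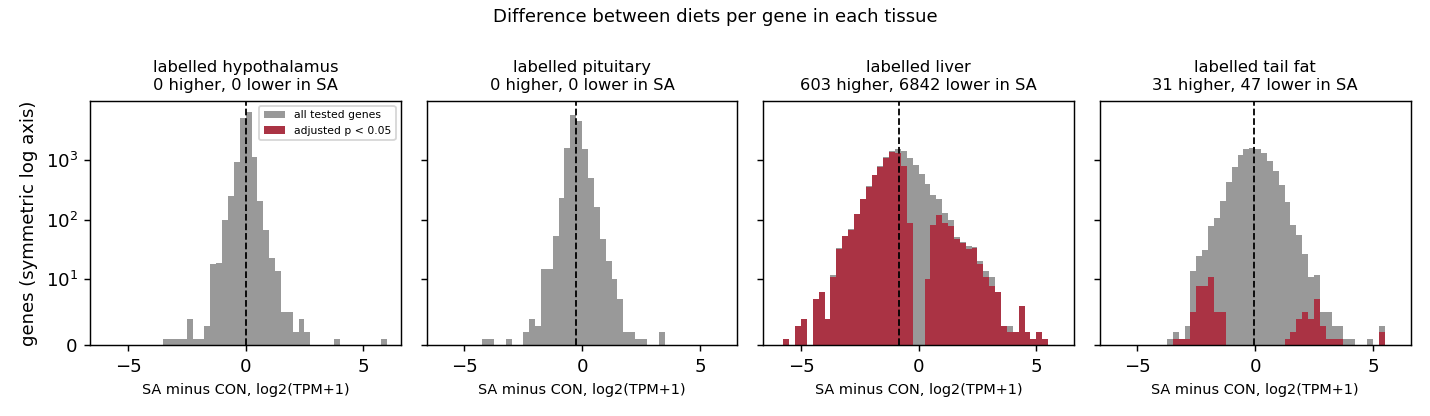
Histograms of the change in log2(TPM + 1), SA minus CON, over all genes tested in each tissue, with genes past an adjusted p of 0.05 in red and the median as a dashed line, without the largest changes, such as that of CCDC152 in liver. The median was −0.83 in liver, where 7445 genes passed, and −0.06 in tail fat, where 78 passed.

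The second comparison asked the same of tissue labelled pituitary. The median change over the 14472 genes tested there was −0.27, and the changes and counts given are not corrected for it. Markers of vessel walls were higher as a group, with 13 of 14 smooth muscle and pericyte genes higher (camera, adjusted p = 1.24e-17, and adjusted p = 0.13 with an estimated correlation), among them smooth muscle actin ACTA2 (change 0.86), RGS5 (0.81) and the myosin MYH11 (0.95). Endothelial genes were higher in 12 of 15 members (adjusted p = 6.43e-15, and 0.13 as adjusted p with an estimated correlation), such as the VEGF receptor FLT1 (0.61) and the tight junction gene CLDN5 (0.59), and macrophage and microglia genes in 12 of 13 (adjusted p = 1.93e-13, and 0.13 in the same way), such as AIF1 (0.48). A list written for pituitary stem and folliculostellate cells was higher in 7 of 9 members (adjusted p = 5.74e-11, and 0.0485 as adjusted p with an estimated correlation), with galectin LGALS3 at 4.14 TPM in CON and 9.82 in SA (0.98, SE 0.31), annexin ANXA1 at 6.85 and 14.1, and ALDH1A1 changing by 0.78. The median anterior pituitary marker stood at 0.03 TPM in these libraries, and these genes are also expressed by other cell types, so the list does not name the cells they came from. Neuronal and synaptic genes were lower in all 28 members (adjusted p = 0.00489, and 0.877 as adjusted p with an estimated correlation), with the vesicular GABA transporter SLC32A1 changing by −1.12 and SYT1 by −0.87.

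The library SA 4 stood apart from the other libraries labelled pituitary. It held 67.4% mitochondrial TPM against 36.4% to 50.6% in the other SA libraries, 496 TPM of GAPDH against 1332 to 2291, and 3081 TPM of TTR against 8.38 to 43.3, while TTR in CON ranged from 25.4 to 465. Without it, 7 lists passed in place of 15, and the median change of all genes was −0.02. With an estimated correlation, the stem and folliculostellate list was the only one that passed.

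Another 10 lists passed in the libraries labelled pituitary with the preset correlation. Mitochondrially encoded genes were higher in 10 of 12 members (adjusted p = 1.81e-12, and adjusted p = 0.204 with an estimated correlation), with ND5 changing by 0.69. Genes of glycolysis were lower in 15 of 16 members (adjusted p = 0.0308, and 0.877 as adjusted p with an estimated correlation), with the aldolase ALDOC changing by −0.60, and genes of the tricarboxylic acid cycle were lower in all 22 members, 5 of them above the median of all genes (adjusted p = 0.0411, and 0.877 in the same way), with MDH2 changing by −0.54. Skeletal muscle genes passed as higher (adjusted p = 2.38e-04, and 0.13 as adjusted p with an estimated correlation) although their median change was −0.04 and their mean 0.25. Of the 7 members, 1 passed adjusted over the list alone, and desmin DES, which is also a smooth muscle gene, went from 2.74 to 5.87 TPM. Ribosomal proteins passed as higher (adjusted p = 2.91e-04, and 0.84 as adjusted p with an estimated correlation) with a median of −0.01, all 32 lying above the median of all genes. Immediate early genes (adjusted p = 0.0106, median −0.09) and inflammatory genes (adjusted p = 0.0411, median −0.03) also passed as higher with negative medians, and collagens (adjusted p = 3.63e-04) had a median of 0.01 and a mean of −0.03. Interferon-stimulated genes (adjusted p = 3.63e-04) and T and NK cell genes (adjusted p = 0.0212, 4 members) passed as higher. With an estimated correlation the adjusted p of these 5 lists was 0.702, 0.613, 0.282, 0.541 and 0.204 in that order. After quantile normalization 4 of these lists no longer passed, mitochondrially encoded genes (adjusted p = 0.886), T and NK cell genes (0.338), inflammatory genes (0.0819) and skeletal muscle genes (0.0712). After removal of mitochondrial and ribosomal RNA, T and NK cell genes did not pass (0.205).

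No gene passed in limma among those tested in the libraries labelled pituitary, with 218 at an unadjusted p under 0.05, and array weights called 165 and the joint fit 4. The smallest adjusted p, 0.0626, belonged to a gene without a name (ENSOARG00020019378), at 4.78 ± 1.63 TPM in CON and 0.47 ± 0.36 in SA (change −1.96, SE 0.28). Among the named genes of smallest p, AIRE (change 1.38, 1.24 to 4.74 TPM), BST1 (1.61, 5.31 to 15.8 TPM), the BMP antagonist GREM1 (1.38), TUT4 (1.19) and C17orf67 (1.12) had higher values in SA. The calcium channel RYR3 (−1.53, 5.46 to 1.09 TPM), HMCN2 (−1.53, SE 0.33, 255 ± 88.8 to 85.8 ± 22.1 TPM), UNC79 (−1.30), FAM187A (−1.30) and AFMID (−1.22) had lower values. These named genes had adjusted p-values between 0.544 and 0.747. PRL, FSHB, TSHB and GHRHR lay below the expression filter.

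In liver, the organ that makes most plasma proteins and glucose, 6842 of 11582 genes tested were lower past the threshold in the SA libraries. Genes of secreted proteins and of metabolism were among them, but only 2 of 33 lists passed against all other genes. Coagulation factor F9 (ENSOARG00020018941) averaged 316 ± 42.0 TPM in CON and 13.8 ± 2.66 in SA (change −4.43, SE 0.24, adjusted p = 1.01e-05), transferrin TF 4993 ± 1125 and 221 ± 46.6 (−4.49), and the complement gene C8A 179 and 9.63 (−4.10). MTTP, which loads lipid onto lipoproteins, averaged 36.5 ± 11.3 TPM in CON and 0.79 ± 0.22 in SA (−4.35, SE 0.22), with 53.3 in CON 1. The succinate dehydrogenase subunits SDHA (ENSOARG00020036938), 116 ± 33.8 and 10.8 ± 1.27 TPM (−3.28, SE 0.25, adjusted p = 3.43e-05), and SDHB, 148 ± 18.9 and 32.3 ± 13.9 TPM (−2.27), which oxidise succinate, both fell. Mitochondrially encoded genes rose, with 10 of 12 members higher past the threshold and 1 lower (camera, adjusted p = 3.99e-13, and adjusted p = 0.407 with an estimated correlation), among them ATP6, from 17318 to 63991 TPM.

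In total 7445 of 11582 genes tested in liver passed, 603 higher and 6842 lower. The median change over all genes was −0.83, the changes given are not corrected for it, and 1905 of the genes that passed lay above that median. After quantile normalization 4326 genes passed, 1886 higher and 2440 lower, and after removal of mitochondrial and ribosomal RNA 3744 passed, 1957 higher and 1787 lower. All liver SA libraries and no liver CON library had the high mitochondrial share, the CCDC152 level over 10 TPM and the low SELENOP level described above, so every change named for liver goes together with these library differences.

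Among lists of hepatocyte genes, 16 of 21 secreted and identity genes fell, such as plasminogen PLG (−3.38) and antithrombin SERPINC1 (1881 to 169 TPM), as did 12 of 17 acute phase genes, such as the fibrinogen chain FGB (18073 to 1842 TPM, −3.31) and CRP (−2.43). Of the genes of the urea cycle and amino acid breakdown, 17 of 29 fell, with CPS1, the entry enzyme of the urea cycle, going from 776 to 80.6 TPM (−3.39), and 10 of 13 genes of xenobiotic metabolism fell, such as CYP3A24 (−2.58) and EPHX1 (−2.97). Of genes of bile acid synthesis and transport, 11 of 18 fell, among them CYP27A1 (−3.46) and the export pump ABCC2 (−2.59), while CYP7A1, the rate-limiting enzyme, did not pass (−0.84, adjusted p = 0.172). The growth hormone receptor GHR fell from 258 to 51.5 TPM (−2.36), as did 14 of 20 genes of the growth hormone and IGF axis, including IGF1R (−1.06) and STAT5B (−1.42, adjusted p = 0.0800 after removal of mitochondrial and ribosomal RNA). None of these lists passed against all other genes, with adjusted p from 0.207 for secreted and identity genes to 0.949 for bile acid genes. After quantile normalization 7 liver lists passed, among them secreted and identity genes (adjusted p = 7.40e-04) and acute phase genes (0.0194) as lower, and after removal of mitochondrial and ribosomal RNA 13 passed, among them these (3.43e-04 and 0.0106) and xenobiotic metabolism (0.0429) as lower. With an estimated correlation, run on the main fit only, these 3 lists each had an adjusted p = 0.984.

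Genes of energy metabolism in liver were mostly lower, as were liver genes in general, of which 6842 of 11582 fell past the threshold. None of the lists in this paragraph passed against all other genes in the main fit. With an estimated correlation, run on the main fit only, each had an adjusted p = 0.984. In the tricarboxylic acid cycle 16 of 22 members fell (adjusted p = 0.0891, 0.0356 after quantile normalization and 0.0106 after removal of mitochondrial and ribosomal RNA), with SDHC at −2.76, SUCLA2 at −2.18 and DLST at −2.32. Of nuclear-encoded genes of oxidative phosphorylation, 33 of 42 fell and 2 rose (adjusted p = 0.269, and 0.173 and 0.0431 under these settings), with ATP5MC3 at −3.18 and UQCRC2 at −2.25. In fatty acid oxidation 18 of 28 fell (adjusted p = 0.513), with ETFDH going from 152 to 14.4 TPM (−3.32). CPT1A, the entry step for fatty acids into mitochondria, changed by −0.91, from 106 to 56.2 TPM, which is −0.08 relative to the median of all genes, and had a change of 0.19 after quantile normalization and 0.14 after removal of mitochondrial and ribosomal RNA. In gluconeogenesis 18 of 24 fell (adjusted p = 0.496, and 0.0381 and 0.00853 under these settings), with MDH1 at −2.62 and FOXO1 at −2.39. G6PC1, the last enzyme of glucose release, averaged 449 ± 564 TPM in CON and 34.1 ± 25.4 in SA (−3.36, adjusted p = 0.0109), with 1290 TPM in CON 1 against 87.3 to 250 in the other CON libraries, and its adjusted p was 0.0563 after quantile normalization and 0.0658 after removal of mitochondrial and ribosomal RNA. PCK1 did not pass (−1.55, adjusted p = 0.0889). In glycolysis 12 of 15 fell (adjusted p = 0.269, and 0.0615 and 0.0429 under these settings), such as GPI (−2.45), and of cholesterol genes 12 of 24 fell (adjusted p = 0.949), such as HMGCS1 (−2.53) and ACAT2 (−2.24). Of genes for fatty acid and triglyceride synthesis, 9 of 22 fell (adjusted p = 0.661), such as ELOVL5 (−2.23), and MLXIPL, a glucose-sensing transcription factor, rose from 8.86 to 17.5 TPM (0.91). FASN and SREBF1 did not pass (−0.07 and −0.68). Among genes of the succinate receptor, carriers and related enzymes 11 of 16 fell (adjusted p = 0.513), with the citrate carrier SLC13A5, which also takes up succinate, changing by −2.40 from 70.4 TPM, and HIF1A at −1.78. The succinate receptor SUCNR1 averaged 1.17 TPM in CON and 0.31 in SA, below the filter.

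Collagens and extracellular matrix were the other list that passed in liver, with 20 of 24 members lower (adjusted p = 0.0271, and adjusted p = 0.984 with an estimated correlation) and a median of −1.79. SPARC went from 179 to 13.3 TPM (−3.69), COL1A1 changed by −2.62, COL1A2 by −2.68 and COL4A1 by −2.28. Markers of other cell types fell as well, with 12 of 15 endothelial genes lower (adjusted p = 0.0891, 0.0120 after quantile normalization and 0.00853 after removal of mitochondrial and ribosomal RNA), such as PECAM1 (−2.61), and 12 of 14 macrophage genes (adjusted p = 0.496), such as CSF1R (−3.03). Of genes of endoplasmic reticulum stress, 14 of 18 fell and 1 rose (adjusted p = 0.411, and 0.0574 and 0.0139 under these settings), with the chaperone HSPA5 going from 404 to 29.9 TPM (−3.60). Of ribosomal proteins, 14 of 32 fell and 1 rose, but against all other genes the list leaned higher (adjusted p = 0.496, and 0.0542 and 0.0106 under these settings). It was the only list that passed as higher after removal of mitochondrial and ribosomal RNA. With an estimated correlation, run on the main fit only, the endothelial, endoplasmic reticulum stress and ribosomal protein lists each had an adjusted p = 0.984. Of core clock genes 12 of 20 fell and 1 rose (adjusted p = 0.949), and of inflammatory genes 4 of 11 fell (adjusted p = 0.706), such as ICAM1 (−1.68), which did not pass under these settings, while NFKBIZ rose from 6.25 to 13.5 TPM (0.98). PER1, PER2 and NR1D1 did not pass in liver. With fry, 32 of 33 lists moved in 1 direction, which reflects a movement of the members and not a comparison with other genes.

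The genes that rose most clearly in liver included 3 rows of 5S ribosomal RNA with identical values and CCDC152 and RCN3, all listed at 0 in every CON library and averaging 1236, 526 and 18.0 TPM in SA. DCHS2, a cadherin, rose from 1.98 ± 0.79 to 59.1 ± 15.3 TPM (4.33, SE 0.27), CCDC191 from 0.25 to 28.0 TPM, FAM174C by 3.05, CNTD1 by 2.56 and ABHD12B by 2.44. The remaining genes of smallest p among those that fell were SEBOX, at 7.66 TPM in CON and listed at 0 in every SA library, PLA1A (−4.22), SSR3 (−4.15), C2orf72 (−4.08), GTF3C6 (−2.82), PTRHD1 (−2.62) and RBM12B (−2.52). The strand setting of the counting is not given, and SEBOX overlaps VTN (3712 TPM in CON and 2394 in SA), CNTD1 overlaps BECN1, ABHD12B overlaps PYGL, PTRHD1 overlaps CENPO, RBM12B overlaps CIBAR1 and SSR3 overlaps KCNAB1 in the RefSeq table, so the levels of these genes are uncertain. The same holds for CCDC152 and RCN3, which lie next to SELENOP and FCGRT (230 TPM in CON and 39.7 in SA), genes that changed the other way, as did the nearest genes to DCHS2 (PLRG1, 15.7 TPM in CON and 2.89 in SA) and CCDC191 (QTRT2, 3.77 and 1.76). A falling neighbour is common in liver, however, where 6842 of 11582 genes tested fell past the threshold.

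**Figure D4:**
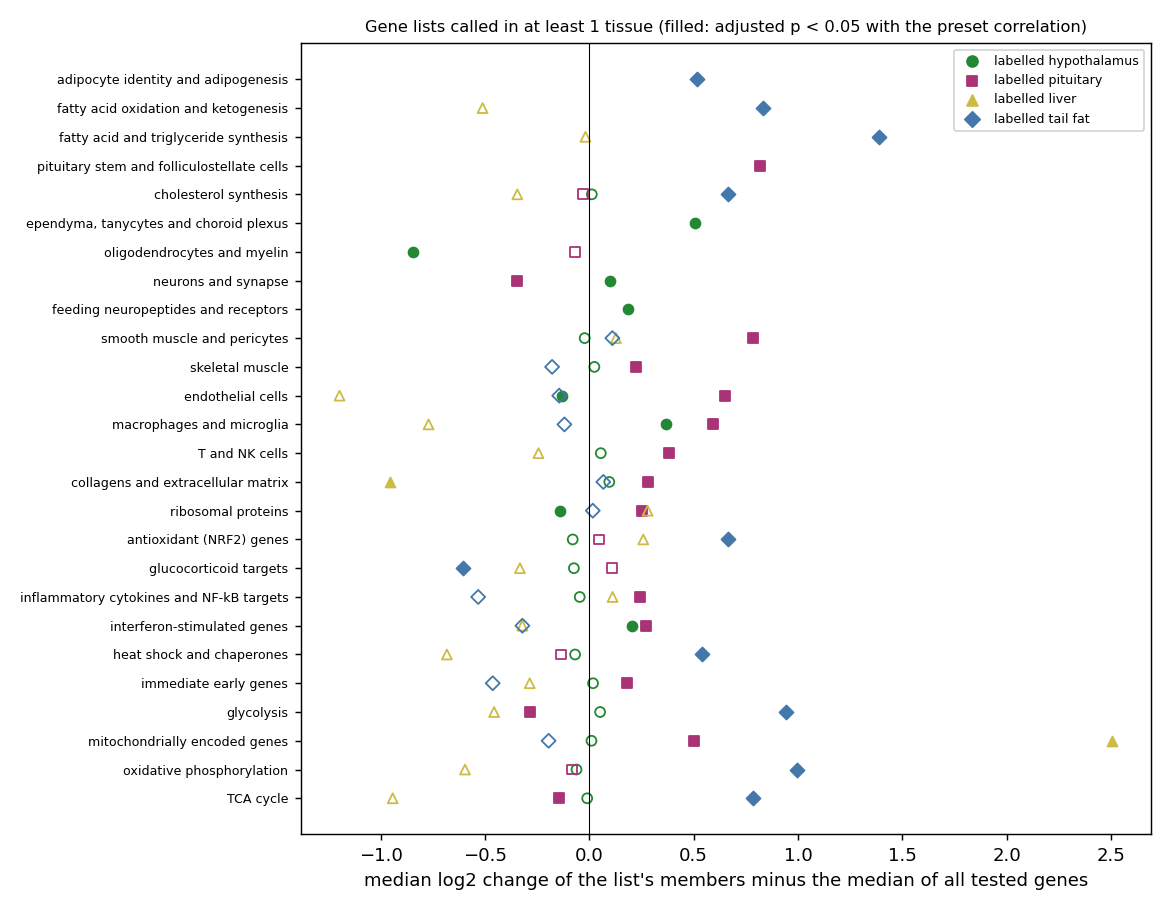
Median change of each gene list minus the median of all genes tested in the tissue (log2 scale), with filled symbols for lists at an adjusted p under 0.05 in camera with the preset correlation. In liver only mitochondrially encoded genes and collagens are filled, at 2.51 and −0.95.

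In tail fat, the fat depot that characterises this breed, the smallest p-values belonged to rises of a water channel and a hormone receptor and to the fall of FAM13A. The water channel AQP5 (ENSOARG00020023923) averaged 2.38 ± 2.52 TPM in CON and 144 ± 111 in SA (change 5.35, SE 0.61, adjusted p = 0.00306), and the secretin receptor SCTR 1.40 ± 1.13 and 28.4 ± 7.18 (3.69, SE 0.45, adjusted p = 0.00383). FAM13A fell from 15.6 ± 7.61 to 0.59 ± 0.24 TPM (−3.26, SE 0.46, adjusted p = 0.0112). Enzymes of metabolism also rose at larger p-values. BCAT2, which starts the breakdown of branched-chain amino acids, averaged 139 ± 87.4 and 907 ± 509 TPM (2.71, SE 0.49, adjusted p = 0.0205), and AGPAT2, an acyltransferase named from the list for triglyceride synthesis, 804 ± 315 and 4359 ± 2139 TPM (2.39, SE 0.49, adjusted p = 0.0403).

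Among 11185 genes tested in tail fat, 78 passed, 31 higher and 47 lower. The others that rose with the smallest p were PPM1L (5.57 to 55.8 TPM), the organic anion transporter SLC22A6 (2.64), TMEM37 (2.51), the ciliary transport gene IFT52 (28.0 ± 5.14 to 153 ± 21.4 TPM), TMEM132E (2.34), FKBP1B (1.76) and TPBGL (2.92). Those that fell included INTU (−2.50), TRIM45 (−2.48), CEP95 (−2.29), ITIH4 (−2.27), CFAP100 (−2.21), LGI1 (−1.91), the homeobox gene HOXD4 (−1.77, 3.80 to 0.40 TPM) and CACNB2 (−1.73), and from the smooth muscle list LMOD1 (−2.11, 11.4 to 1.89 TPM). SCTR and TMEM37 are neighbours, while FKBP1B overlaps WDCP, CACNB2 overlaps NSUN6 and another gene, and FAM13A and PPM1L each overlap an uncharacterised gene, so the levels of these 4 genes are uncertain. Among nearest genes without overlap, HSD17B14 by BCAT2 (2.69 to 17.7 TPM), SGK2 by IFT52 (20.6 to 76.6) and AQP6 by AQP5 (0.03 to 1.48) also rose. MUSTN1 by ITIH4 also fell (461 to 111 TPM). CCL1 by TMEM132E (7.93 to 1.43 TPM) and ARRB1 by TPBGL (2.79 to 2.20) moved the other way. Whether reads were shared with neighbours was not tested. The libraries CON 2 and SA 1, 1 per diet, had the low CCDC152 and high SELENOP described above. The count was 8 without SA 3, 10 without CON 1, 20 without CON 4, 20 without SA 4, 47 without SA 1 and 314 without CON 2, while AQP5, SCTR, PPM1L and FAM13A passed whichever library was left out. With no expression filter no gene passed in limma, with 2588 at an unadjusted p under 0.05, and after removal of mitochondrial and ribosomal RNA 1362 passed, 167 higher and 1195 lower. Quantile normalization gave 415 genes, the replicate block 413, the joint fit 2014 and array weights 2839, so the count depends strongly on the setting.

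**Figure D5:**
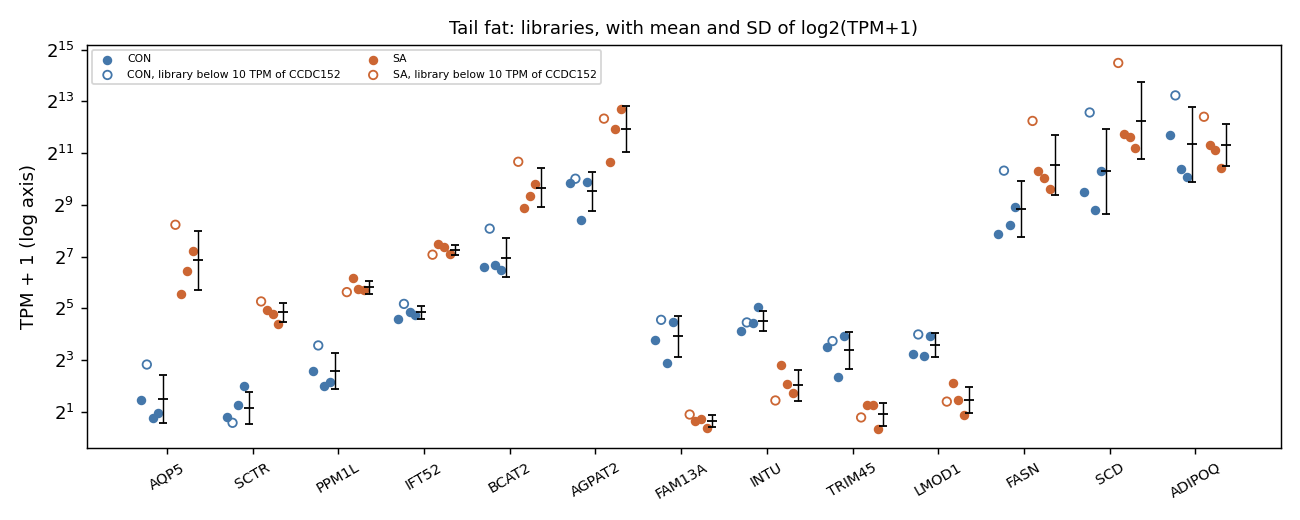
TPM + 1 (log axis) of 13 genes in the 8 tail fat libraries, with the mean and SD of the log2 values for each diet and open circles for CON 2 and SA 1, the libraries under 10 TPM of CCDC152. AQP5 lies at 0.69 to 6.10 TPM in CON and 45.4 to 299 TPM in SA.

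Gene lists of energy and lipid metabolism were higher in tail fat with SA at the preset correlation. Each of the 10 lists that passed, given here, had an adjusted p = 0.996 with an estimated correlation. All 42 measured nuclear-encoded genes of oxidative phosphorylation were higher (camera, adjusted p = 3.17e-15, median change 0.93), with 6 passing adjusted over the list alone, such as UQCRFS1 (34.3 to 122 TPM) and NDUFV1 (122 to 330 TPM). Of genes for fatty acid and triglyceride synthesis, 19 of 21 were higher (adjusted p = 1.25e-07), with AGPAT2 passing over all genes and 9 passing adjusted over the list alone, among them the citrate exporter SLC25A1 (change 2.02), DGAT2 (2.05) and the lipogenic regulator SREBF1 (2.10). All 12 genes of glycolysis were higher (adjusted p = 1.13e-04), 3 of them adjusted over the list alone, with GAPDH at 1.50, ENO1 at 1.75 and ALDOA at 1.17. In the tricarboxylic acid cycle 20 of 22 were higher (adjusted p = 2.19e-04), such as MDH2 (1.49) and SDHC (1.58), none of them passing alone. Antioxidant genes were higher in 17 of 19 (adjusted p = 6.07e-04), 5 adjusted over the list alone, such as GPX4 (1.24), and cholesterol synthesis genes in 20 of 24 (adjusted p = 9.61e-04), such as MVD (1.67). Fatty acid oxidation genes were higher in 21 of 26 (adjusted p = 0.00229), such as the carnitine carrier SLC25A20 (1.68), adipocyte identity genes in 16 of 22 (adjusted p = 0.0307), with AGPAT2 the member that passed, and heat shock genes in 12 of 14 (adjusted p = 0.0398), such as HSPB1 (0.88). Glucocorticoid targets were lower in 14 of 16 (adjusted p = 0.00229), with PDK4, a brake on glucose oxidation, changing by −2.35, DUSP1 by −1.37 and ZBTB16 by −1.67. After quantile normalization 4 of them no longer passed, adipocyte identity genes (adjusted p = 0.629), heat shock genes (0.371), antioxidant genes (0.0793) and fatty acid oxidation (0.0590). Ribosomal proteins (1.01e-04) and immediate early genes (0.0308) then passed as lower at the preset correlation. With an estimated correlation, run on the main fit only, both had an adjusted p = 0.996.

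The panel genes of tail fat did not pass. The fatty acid synthase FASN averaged 572 ± 482 TPM in CON and 1988 ± 1915 in SA (1.72, SE 0.60, adjusted p = 0.219), and the desaturase SCD changed by 1.97 (adjusted p = 0.336), both with their highest value in SA 1. Lipoprotein lipase LPL changed by −1.26, SDHA by 0.98, SDHB by 0.76, and adiponectin ADIPOQ by −0.02. Leptin LEP, LIPE, PNPLA2, PPARG, UCP1, PER1, PER2 and NR1D1 did not pass, and SUCNR1 averaged 0.99 TPM in CON and 0.31 in SA, below the filter. Lists of lipolysis (adjusted p = 0.225), thermogenic genes (adjusted p = 0.0886) and the core clock (adjusted p = 0.988) did not pass.

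Whether the effect of diet differed between tissues was tested over all 32 libraries. Of 16360 genes, 4414 had an interaction past the threshold. Among genes with a name, the smallest adjusted p belonged to SEBOX (4.61e-16), the coagulation genes F12 (9.47e-13) and F9 (8.50e-12), the complement genes C8A (2.27e-11) and C8B (3.13e-10), DCHS2 (2.03e-10), the transporter ABCC6 (1.39e-09) and MTTP (1.80e-09). These genes stood at no more than 4.67 TPM in any library outside liver. For all of them but DCHS2, which rose, a fall of the size seen in liver was therefore not possible there. The test takes 1 spread per gene over all tissues. Levels near 0 outside liver can make that spread smaller than the spread in liver, so these p-values can be too small. SCTR, which was expressed in liver at a mean of 10.3 TPM, changed by 3.69 in tail fat and 0.01 in liver (2.97e-09), and PLA1A, at means of 11.8 and 18.3 TPM in the libraries labelled hypothalamus and pituitary, changed by −4.22 in liver and by 0.09 and 0.21 in those (3.29e-09). Of the 4414 genes, 3223 passed the filter in all 4 tissues, and a test of only the 9228 genes that did so called 3602. SDHA changed by −3.28 in liver and 0.98 in tail fat (adjusted p = 4.59e-04) and SDHB by −2.27 and 0.76 (adjusted p = 5.03e-04). PER1, PER2 and NR1D1 did not pass (adjusted p = 0.369, 0.442 and 0.416). Without the liver libraries 205 genes passed, array weights gave 10046, and leaving out CON 1, CON 4 or SA 3 in all tissues gave 2508, 2606 or 2801.

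Few genes changed in the same direction in more than 1 tissue. Among 9690 genes tested in liver and tail fat, 2 fell in both, the plasma protein gene ITIH4 (−2.25 in liver and −2.27 in tail fat) and a gene without a name, where 21.1 would be shared by independent lists of these sizes. No gene rose in both, against 0.76 for independent lists, and no other pair of tissues shared a gene because no gene passed in the brain libraries. Liver and tail fat shared 17 after quantile normalization, 450 with array weights, 301 in the joint fit and 37 after removal of mitochondrial and ribosomal RNA, where 64.2, 762, 566 and 163 would be shared by independent lists.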

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

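The tests of a library state, of the strand setting and of dietary succinic acid in liver and the tests of the brain labels were chosen after those results were seen, as were the test of the tail fat state on 6 libraries, which replaced a test by a covariate with limits set beforehand, and the simulation of HOX genes with the size of change that decides it, and the tail fat fit with a covariate was chosen after seeing the data (its splits were run after its count was known), while the other tests of this part were fixed before their results.

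The pattern most in need of follow-up is that 7445 liver genes differed between SA and CON libraries. Of the 35 splits of the 8 liver libraries into 4 and 4, only the diet split called that many, and the highest other split called 3. A share of 1 in 35 is the smallest this test allows, and it was not adjusted for the other split tests. It argues against chance but does not exclude it. Across 9690 genes, the liver change correlated at −0.679 with the deviation of tail fat CON 2 and at −0.607 with that of tail fat SA 1 from the other libraries of their diet, so a library state that occurs within each diet in tail fat may account for much of the liver difference. Mitochondrial and ribosomal RNA taking up the TPM scale stays open as a partial source of the calls, because 31.3% of the genes kept their call and direction without these transcripts, between the limits of 10% and 50% set before. The median change over all liver genes went from −0.83 to −0.01 without these transcripts. It was −0.09 after quantile normalization, which equalizes the distributions of the libraries and so brings the median near 0 whatever the cause. By the removal of these transcripts, the shift of the median goes with the TPM scale, while the source of the calls that remain is open. A strand setting of the counting that differs between the liver libraries of both diets also stays open. Of 82 genes partly overlapped by an abundant gene, 4.88% rose by more than 1 in SA (95% interval 1.34% to 12.0%). At the same level 1.68% was expected (Fisher's exact test over genes, p = 0.0510). The observed share lies below the 50% this explanation was taken to need. The rises were not corrected for the median change of −0.83, however, which makes 50% harder to reach. The interval also exceeds 2 times the expected share, the limit against the explanation. In reverse, 27.3% rose in CON against 30.3% expected (Fisher's exact test over genes, p = 0.744), which lends it no support. In tail fat, 4.85% rose in the 6 libraries against CON 2 and SA 1, with 0.77% expected (Fisher's exact test over genes, p = 0.00141). In these Fisher tests the comparison counts were set from the expected share, not observed, and genes were treated as independent. Their p-values are therefore approximate. The gene table used gives neither strands nor exons, so the share that would rise is not known. Dietary succinic acid cannot be told apart from the library state, because 4 liver SA libraries and 0 liver CON libraries had CCDC152 over 10 TPM.

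The next pattern is the set of 78 tail fat genes that part SA from CON, for which chance cannot be excluded, because 2 of 35 splits called as many and the other one, which put CON 1, CON 3, CON 4 and SA 4 against the rest, called 187. The library state of CON 2 and SA 1 was tested by leaving these libraries out. In the other 6, 98.7% of the genes stayed called in the same direction, with a median absolute change of 2.22 against 2.19 in all 8. The calls therefore did not need CON 2 and SA 1. Each diet holds 1 library of this state, however, and the genes were chosen on these same libraries. The test could therefore hardly come out otherwise, and no cause is argued against. The covariate test also kept 77 genes, but the state is balanced between the diets, so the design fixes its estimates. Another body position of the fat stays open: 0 of the HOX genes other than HOXD4 passed over the 19 HOX genes alone, which met the limit set beforehand, but that limit was wrong for small changes, because with 3 of these genes changed in simulated data the same test recovered 22.5% of changes of 1 and 82.5% of changes of 2. Any HOX gene other than HOXD4 passed in 48.5% of simulations with changes of 1, the size taken to decide after the count was known, and in 100% with changes of 2, the size used before, so the count speaks against changes of 2 in 3 of these genes. A genetic difference between the sheep of both diets that acts in all tissues also stays open, because the tail fat change correlated at 0.251 with the change in libraries labelled hypothalamus (53 genes), between the limits of 0.2 and 0.5, although it correlated at −0.134 in those labelled pituitary (55 genes), below both limits.

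The last pattern is that libraries labelled hypothalamus and pituitary lack the hormones of those tissues. An exchange of both labels is argued against by a median of 0.0113 TPM for anterior pituitary markers in the libraries labelled hypothalamus. The median striatum marker stood at 187 TPM in the libraries labelled hypothalamus and 5.86 TPM in those labelled pituitary, so the former may hold striatum. The median marker of thalamus and midbrain stood at 4.49 TPM in the libraries labelled pituitary and 0.11 TPM in those labelled hypothalamus. Of the 13 markers found, 10 were higher under the label pituitary. PRKCD (4.49 against 9.72 TPM), TH (0.07 against 0.47) and SLC6A3 (0.03 against 0.11) were lower there. The libraries labelled pituitary may hold tissue of thalamus or midbrain, but the markers do not all point that way. For this pattern no biological explanation was tested.

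Splits of the libraries were counted for the other results too. For genes in the libraries labelled hypothalamus and pituitary the diet split called 0, so all 35 splits call as many whatever the data and nothing follows about chance (the highest other called 3 and 17). For gene lists chance cannot be excluded, with 16 of 35 splits as high in the libraries labelled hypothalamus (real 8, highest other 14), 5 in those labelled pituitary (real 15, highest other 16), 35 in liver (real 2, highest other 15) and 13 in tail fat (real 10, highest other 14). For the 763 tail fat genes called with the library state as a covariate, 1 of 20 splits called as many, the real one, with 8 as the highest other, which is too few splits for a share under 0.05. For the 4414 genes with an interaction, 2 of 100 regroupings of diet within tissues called as many, the real one included. That share lies under 0.05, but the other regrouping called 4629, more than the real one. Whether the other regrouping kept the diet split of liver was not recorded, and 205 genes passed without liver. Each tissue was regrouped apart, although the labels do not say whether a number marks 1 sheep in all tissues. Chance is therefore not excluded.

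A library was singled out where its gap to the nearest of the others of its group took up more of the range of the group than Dixon's 95% limit for 4 values. This picked 30 of 236 groups, where chance picks about 1 in 20, or 11.8. Among library measures, pituitary CON 1 had 15178 genes at 1 TPM or more against 14254 to 14370 (share of the range 0.874), liver SA 4 had 10611 against 10216 to 10232 (0.959), and 5S and 5.8S RNA held 0.171% of TPM in tail fat CON 2 against 0.633% to 0.666% (0.933).

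In the libraries labelled hypothalamus, CAVIN2 stood at 16.6 TPM in CON 3 against 7.39 to 8.51 (0.878), H2AC6 at 1.13 in CON 2 against 2.60 to 2.90 (0.831), MMGT1 at 17.7 in SA 4 against 10.9 to 12.0 (0.845), and a signal recognition particle RNA at 1.99 in CON 1 against 1.34 to 1.43 (0.862) and at 1.08 in SA 2 with the others listed at 0 (1). In those labelled pituitary, POMC stood at 4.89 in CON 2 against 2.66 to 3.03 (0.834). In liver, FAM174C stood at 0.51 in CON 4 with the others listed at 0 (1), FASN at 1.95 in CON 1 against 0.99 to 1.13 (0.854), G6PC1 at 1290 in CON 1 against 87.3 to 250 (0.864), MTTP at 53.3 in CON 1 against 29.7 to 32.5 (0.881), and PTRHD1 at 1.85 in SA 3 against 2.15 to 2.21 (0.833).

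In tail fat CON 2, BCAT2 stood at 270 TPM against 88.6 to 100 in the other CON libraries (0.936), LEP at 140 against 22.6 to 34.6 (0.897), SCD at 6075 against 444 to 1259 (0.855), SDHA at 194 against 16.4 to 42.0 (0.855) and UCP1 at 2.45 against 0 to 0.39 (0.841). In tail fat SA 1, FASN stood at 4846 against 780 to 1263 in the other SA libraries (0.881), PER1 at 24.1 against 5.53 to 6.57 (0.944), PNPLA2 at 735 against 222 to 308 (0.834), SCD at 22909 against 2336 to 3392 (0.949), SDHA at 353 against 33.9 to 79.0 (0.858) and TMEM37 at 11.5 against 7.52 to 8.01 (0.878). Elsewhere in tail fat, AGPAT2 stood at 337 in CON 3 against 919 to 1030 (0.840), PNPLA2 at 158 in CON 3 against 245 to 260 (0.857), NR1D1 at 16.7 in CON 4 against 7.41 to 8.44 (0.889), PPM1L at 71.6 in SA 2 against 48.4 to 52.2 (0.836), and HOXD4 was listed at 0 in SA 4 against 0.50 to 0.56 (0.893).

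The difference between SA and CON libraries itself differed between tissues by the interaction test for SEBOX (adjusted p = 4.61e-16), F12 (9.47e-13), F9 (8.50e-12), C8A (2.27e-11), DCHS2 (2.03e-10), C8B (3.13e-10), ABCC6 (1.39e-09), MTTP (1.80e-09), SCTR (2.97e-09), PLA1A (3.29e-09), SDHA (4.59e-04) and SDHB (5.03e-04). SCTR moved in tail fat, PLA1A, SDHA and SDHB moved in liver, and the other 8 moved in liver and stood at no more than 4.67 TPM in any library of another tissue. The test takes 1 spread per gene over all tissues, so the p-values of these 8 can be too small. For all but SCTR the largest change was in liver, where it goes together with the library state. SDHA and SDHB also changed the other way in tail fat (0.98 and 0.76), where neither passed.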

How the results depend on the processing

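Removal of mitochondrial and ribosomal RNA, the tail fat fits on 6 libraries and with a covariate, all settings of the overlap, and the interaction with quantile normalization, array weights, only genes expressed in all tissues and without liver were chosen after seeing the data. Where a value below differs from the report, the cause was not tested. Depth is unknown for TPM, so its effect on genes of low expression was not measured, and the alternatives that need counts (other size factors, voom weights and a Wald test on counts) were not run.

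With quantile normalization, 4326 liver genes (1886 higher, 2440 lower, 3042 shared with the 7445), 415 tail fat genes (66 shared with the 78) and 7 liver lists passed. With no filter, 0 tail fat genes passed in limma (2588 at an unadjusted p under 0.05). With a filter at 5 TPM, 4618 liver genes (4567 shared; fewer genes were tested), 27 tail fat genes, 5 lists in the libraries labelled hypothalamus and 1 liver list passed. Array weights called 165 genes in the libraries labelled pituitary, 2839 in tail fat (1466 higher, 1373 lower) and 10046 with an interaction, and the joint fit of 32 libraries called 3, 4 and 2014 genes in the libraries labelled hypothalamus, those labelled pituitary and tail fat. Without mitochondrial and ribosomal RNA, 3744 liver genes (1957 higher, 1787 lower, 2331 shared), 1362 tail fat genes (167 higher, 1195 lower, median change −0.40) and 13 liver lists passed. The fit on 6 tail fat libraries called 398 genes and the covariate 763, with 77 of the 78 kept in each, and 205 genes had an interaction without liver.

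With an estimated correlation, 0 lists passed in the libraries labelled hypothalamus, 1 in those labelled pituitary, 0 in liver and 0 in tail fat, and with fry 0, 0, 32 and 0. The direction turned with fry for 4 lists in the libraries labelled pituitary, immediate early genes (adjusted p = 0.857), inflammatory genes (0.941), ribosomal proteins (0.941) and collagens (0.981). CPT1A in liver changed by 0.19 with quantile normalization and 0.14 without mitochondrial and ribosomal RNA, against −0.91.

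The number of genes shared between tissues, summed over pairs of tissues, was 17 with quantile normalization, 0 with no filter, 1 at 5 TPM, 479 with array weights (450 of liver and tail fat, 15 of liver and pituitary, 14 of pituitary and tail fat), 302 in the joint fit (301 of liver and tail fat, 1 of liver and pituitary), 39 with the replicate block and 37 without mitochondrial and ribosomal RNA.

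The replicate block called 413 tail fat genes (all 78 kept) and otherwise moved no count by over 1.5 times, apart from the overlap. The CON and SA libraries of the same number deviated together (correlation over 0.1) in 1, 0, 1 and 2 of 4 pairs in the order of tissues above, so the numbers do not act as a pairing.

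Leaving out 1 library gave 0 to 2 genes and 3 (CON 3 or CON 4) to 10 lists in the libraries labelled hypothalamus, 0 to 1 genes and 7 (SA 4) to 16 lists in those labelled pituitary, 6793 to 7590 genes and 1 (CON 1 or CON 4) to 3 lists in liver, 8 (SA 3) to 314 (CON 2) genes and 8 to 13 lists in tail fat, and 2508 (CON 1 in all tissues) to 5537 genes with an interaction. The genes that passed in the brain libraries did so without CON 3 (1) and SA 2 (2) for the label hypothalamus and without CON 2, CON 3, SA 2 or SA 3 (1 each) for the label pituitary.

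Of 155 named liver genes and lists, 25 lost their call with quantile normalization and 37 without mitochondrial and ribosomal RNA (of those given in the texts, G6PC1, ICAM1, SGK1 and STAT2 in both and STAT5B in the latter). Of 46 in tail fat, 6 lost it with quantile normalization and 4 at 5 TPM. With no filter, all 22 named tail fat genes that had passed lost their call, and lists were not run. The totals of 155 and 46 include panel genes that did not pass and so had no call to lose. Some of the named genes were not tested at 5 TPM or after the removal. Sign changes were counted for named genes that passed in neither fit, against all fits of named genes, passing or not. They numbered 19 of 327 in the libraries labelled hypothalamus, 5 of 250 in those labelled pituitary, 16 of 2412 in liver and 15 of 639 in tail fat. In liver and tail fat, where named genes passed, the share among genes that passed in neither fit is higher. No other named gene past the threshold turned direction. Of the liver genes called in both fits, 3042 with quantile normalization and 2331 without mitochondrial and ribosomal RNA, 0 had the opposite direction, and the direction of genes called in only 1 of the fits was not compared.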

Other observations

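The brain region markers and the test on ND1 were chosen after some of their values had been seen.

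The libraries of both brain labels held transcription factors that mark brain regions. In the libraries labelled pituitary, OTX2, a factor of the developing midbrain and forebrain, averaged 31.5 ± 20.7 TPM (SD, n = 8) against 0.87 in the libraries labelled hypothalamus, TCF7L2 44.8 ± 50.9 against 6.69, TAL1 10.7 against 0.86, GATA3 9.01 against 0.13, BARHL1 7.75 against 0.01 and SOX14 7.46 against 0. LHX9, listed as a hypothalamus marker, averaged 13.3 TPM there and stood at no more than 0.01 in any library labelled hypothalamus. Of the thalamus and midbrain markers, PRKCD, TH and SLC6A3 were lower in the libraries labelled pituitary than in those labelled hypothalamus. In the libraries labelled hypothalamus, the dopamine receptor DRD2 averaged 51.8 TPM against 3.62, and the tachykinin gene TAC1 748 against 291.

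Other gene groups of liver were lower in the SA libraries, which also differed in mitochondrial share and CCDC152. None of the lists given here passed in the main fit, where each had an adjusted p = 0.984 with an estimated correlation. Of 14 heat shock genes 11 fell (adjusted p = 0.269, and 0.0139 after removal of mitochondrial and ribosomal RNA), such as HSP90AA1 (−2.53), STIP1 (−2.79) and HSPA8 (−2.35). Of 17 glucocorticoid targets 12 fell (adjusted p = 0.661), such as PDK4 (−2.95) and SGK1 (−2.86, adjusted p = 0.0521 after quantile normalization and 0.0692 after this removal), of 21 hypoxia targets 13 (adjusted p = 0.496), such as PGK1 (−2.09) and ENO1 (−2.13), and of 20 immediate early genes 12 (adjusted p = 0.883), such as MYC (−3.13). Of 11 T and NK cell genes 9 fell (adjusted p = 0.656, and 0.0360 after the removal), such as CD3D (−1.50), of 22 interferon-stimulated genes 10 (adjusted p = 0.880), such as STAT2 (−1.56, adjusted p = 0.109 and 0.210 under these settings), and of 10 cell cycle genes 8 fell and 1 rose (adjusted p = 0.661), with PCNA at −1.93.

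The mitochondrial gene ND1 was lowest in SA 2 in every tissue, at 4543 TPM against 16364 to 16931 in the other SA libraries labelled hypothalamus, 4447 against 17566 to 25575 in those labelled pituitary, 12172 against 24041 to 30094 in liver and 6753 against 12965 to 28092 in tail fat (exact permutation p = 0.0156). The SA number may mark 1 sheep in all tissues, but this hypothesis was found and tested on the same values, so the p-value lends it no support. For CON the lowest values were 3429 TPM in liver CON 1 and 2868 TPM in tail fat CON 2. Over all genes, SA libraries deviated most like the library of their own number in another tissue in 16 of 24 comparisons and CON libraries in 4 of 24.

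In tail fat CON 4, albumin ALB stood at 473 TPM against 1.54 to 11.3 in the other CON libraries, and TTR at 69.7 TPM with the others listed at 0.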
